A study of Mus musculus with 6 samples.

How the data were processed

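Total RNA was measured in 6 libraries of primary mouse cortical neurons, in 3 groups of 2: a control at 37 °C, cells heated at 42 °C for 15 min, and cells heated at 42 °C for 60 min. Per the labels' protocols, libraries were made with a kit that removes ribosomal RNA instead of selecting poly(A) tails, and reads were single-end and 100 bp long. Per the submitters' processing notes, the tools were kallisto and sleuth and the genome build was GRCm39. Their versions, the annotation release, the use of strand and the way in which transcripts were summed to genes are not given in the sources used here. Reads of genes that overlap on opposite strands were therefore taken as not separable. RNA recovered with ribosomes, which the series also describes, was not analysed here.

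The table held 1 value per gene and library for 55538 Ensembl genes. The authors deposited a normalised signal, which its name calls TPM, but the column totals ran from 892768 to 1056380, so each library carries a further factor beyond TPM. How that factor was made is not stated. The values are not read counts and the sequencing depth of each library is unknown, so no interval or detection limit that needs depth was computed. Column names gave a group and a suffix, s1 or s2. Which of the 2 samples of a group each suffix stands for could not be settled, so columns were assigned to groups only, and s1 and s2 serve as names.

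A table of Ensembl IDs named 52028 of the 55538 genes. Gene classes, neighbouring genes and 3′ UTR sequences came from the GENCODE annotation of the earlier build GRCm38. Since that is not the authors' build, no coordinates are given. Some symbols, such as Hist1h1c, are older ones.

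The test, the gene lists, the rule for naming genes and all alternatives except 1 of scaling were chosen before the data were examined. Values were taken as log2(value + 1), and the 21954 genes with a mean of at least 1 over the 6 libraries were tested. limma 3.58.1 in R 4.3.3 was fitted to all 6 libraries with group as the only term and with a mean-variance trend, which left 3 residual degrees of freedom. Each of the 3 contrasts was tested two-sided with Benjamini-Hochberg adjustment over all genes tested, at an adjusted p of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. Gene lists, 32 in all and each with at least 5 measured members, were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and members were also adjusted over the list alone. Camera with an estimated correlation and fry were alternatives.

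The plan assumed plain TPM and set median-of-ratios scaling as the main scaling. Because the deposited values proved to be scaled per library already, they were used as deposited and that scaling became an alternative, which was decided before any test was run. Other alternatives were pseudocounts of 0.1 and 5, no filter or a mean of at least 5, quantile normalisation, rescaling without mitochondrial and small RNA genes, a replicate block, limma without the trend or with robust estimation, a fit of only the 4 libraries compared, an adjusted p of 0.1, and leaving out each library in turn. Median-of-ratios scaling over the tested genes was chosen after seeing the data, as were 10000 random lists matched on mean expression to the chaperone and histone lists, drawn for each member from the 100 nearest genes on each side. These random lists drew genes independently, which makes their range too narrow for genes that vary together.

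The rule named, per comparison, up to 10 genes with the largest rise and 10 with the largest fall among genes past the threshold with a mean of at least 5 in the higher group and no overlap between groups. Where fewer than 5 genes passed, the 10 with the smallest unadjusted p were taken. The lists described are those past camera and, in each comparison, those of the integrated stress response, the unfolded protein response, immediate early genes and elongation. In lists described by their members, which are not all of them at 15 min or between 15 and 60 min, up to 2 members per direction past the threshold were named, or the 2 with the smallest unadjusted p, and 22 genes of heat shock, early response and translation were always named. Hspe1, Dnaja4, Ier5, Gas1, Eomes, Neurog1, Neurog2, Sox2, Bbc3, Sesn1, Hist1h1b, Hist1h2ac, Jun and Polg, and Rgs2, Malat1, Miat and Cebpg in some comparisons, fell outside it and were chosen after their values were seen. Called genes without a symbol were counted and not named, and 1 gene that the rule names is not reported here.

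The gene test was tested on simulated data in 10 runs with 200 of 21954 genes changed in the simulated 60 min group. In the contrast of 60 min with control it recovered 6.27% of genes changed by 1 on the log2 scale, 60.9% of those changed by 2 and 92.9% of those changed by 4, with a mean of 8.8 false calls. In the contrast of 15 min with control, where no gene was changed, it made a mean of 0.3 calls. The simulation gave all groups the same normal spread, whereas the control libraries differed more than the heated ones. These rates may therefore not hold for contrasts with control. The labels do not say whether the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. An exact permutation test of 2 libraries against 2 cannot go below p = 0.333. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.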

Results

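Neurons dissociated from the cortex of C57BL/6 mouse embryos at day 14.5 were rested for 2 h and then kept at 37 °C or moved to 42 °C. Heat lasted 15 or 60 min, and the control stayed at 37 °C for 60 min. No control of 15 min is described, so differences of the 15 min group from control or from 60 min may include time in culture. Total RNA was sequenced from 2 libraries per group, 6 in all. The series concerns translation elongation and the integrated stress response under heat shock, and the comparisons ask which transcripts differed after each time at 42 °C. Values are the authors' normalised signal per gene, and the depth of each library is unknown.

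Transcripts of young neurons and of neural progenitors were abundant in every library, and the sums over marker lists of other cell types were lower. The summed signal of 25 pan-neuronal and axonal genes ran from 2739 to 4029.6 over the libraries and that of 19 progenitor and radial glia genes from 3132 to 4179.9. The sums were 457 to 711 for astrocyte genes, 278 to 518 for erythroid genes, 175 to 221 for fibroblast and meningeal genes, 29.6 to 42.4 for 19 microglial and macrophage genes and 36.8 to 55.5 for 18 endothelial and mural genes. Single members carried much of some sums. Among the astrocyte genes, Fgfr3 and Id3, which progenitors also express, ran from 89.0 to 230.1 and from 46.6 to 134, and Gfap and Aldh1l1 from 0.711 to 6.42 and from 0.908 to 5.29. Among the fibroblast and meningeal genes, Fn1 ran from 109 to 161 and Col1a1 from 1.004 to 4.67. These 6 genes were chosen after their values were seen. Control library s1 stood apart, with 29309 genes at 1 or above against 19035 to 21796 in the other libraries. It had 5429 long non-coding RNA genes at 1 or above, against 2625 to 3410 elsewhere, and 4100 pseudogenes, against 1467 to 2082. Its abundant genes were lower: among genes with a mean of at least 20, the median ratio to the geometric mean of the libraries was 0.893, against 0.961 to 1.08. In control s2, mitochondrial ribosomal RNA took 12.9% of the signal, against 3.87% to 9.39% elsewhere. On the log2 scale the difference between the 2 libraries of a group had an SD across genes of 0.867 in control, 0.525 at 15 min and 0.607 at 60 min.

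**Figure D1:**
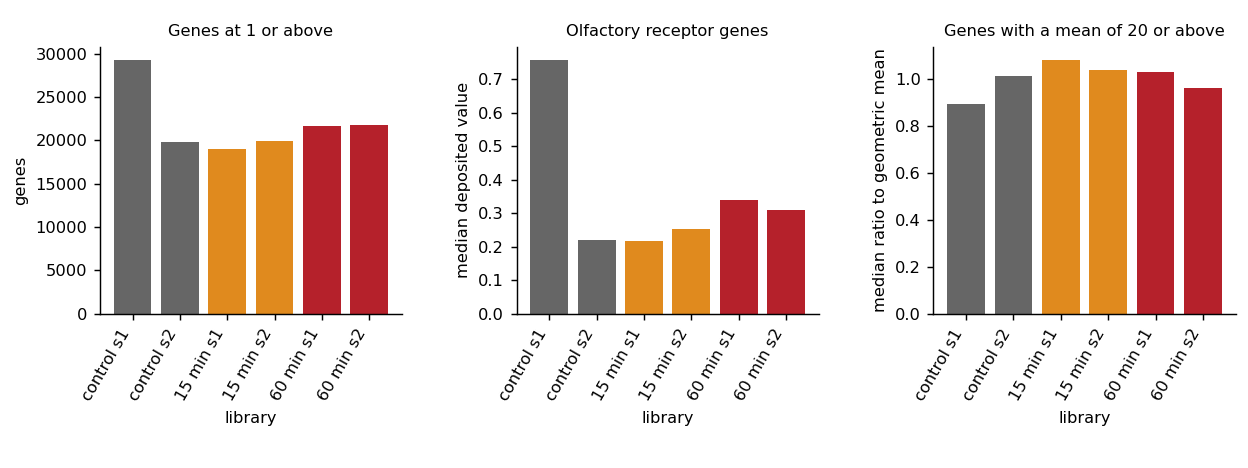
Each bar is 1 library: the number of genes at 1 or above, the median deposited value of 1093 olfactory receptor genes, and the median ratio to the geometric mean of the libraries among genes with a mean of 20 or above. Control s1 has 29309 genes at 1 or above and an olfactory receptor median of 0.759, against 0.218 to 0.339 in the other libraries.

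After 60 min at 42 °C, inducible Hsp70 transcripts had the largest rises of the genes that passed. Hspa1a (ENSMUSG00000091971), an inducible cytosolic Hsp70, rose from 2.06 ± 0.743 in control to 753 ± 57.6 (SD, n = 2 each), and its near-identical copy Hspa1b (ENSMUSG00000090877) rose from 1.91 ± 0.127 to 653 ± 30.0. Reads can be divided between these copies, and their sum was 3.97 ± 0.616 in control and 1407 ± 87.5 at 60 min. Hsph1 (ENSMUSG00000029657), an Hsp110 chaperone that works with Hsp70, rose from 84.9 ± 12.5 to 433 ± 52.2. Btg2 (ENSMUSG00000020423), an antiproliferative gene expressed in neurogenic progenitors, fell from 41.2 ± 3.35 to 9.40 ± 0.263.

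In all, 9 of 21954 genes passed limma's test, 6 higher and 3 lower. An unadjusted p under 0.05 was found for 1830 genes, 642 higher and 1188 lower, against 1097.7 by chance. With median-of-ratios scaling over all genes above 0 it was found for 979, and with a replicate block by suffix for 2758. The median log2 change of all genes was −0.12, and 0.037 without control s1. The log2 fold change was 7.96 ± 0.28 (SE) for Hspa1a (adjusted p = 0.00066), 7.81 ± 0.22 for Hspa1b (adjusted p = 0.000272), 2.34 ± 0.20 for Hsph1 (adjusted p = 0.0444) and −2.02 ± 0.18 for Btg2 (adjusted p = 0.0453). Rnu3a, a U3 small nucleolar RNA, was listed at 0 in the control and 15 min libraries and at 41.4 and 58.9 at 60 min (adjusted p = 0.00355). Snora57, a small nucleolar RNA, fell from 49.9 ± 6.43 to 8.69 ± 0.272 (adjusted p = 0.0444). Such RNAs are short and have similar copies, so their values are uncertain. Gm10616 and Gm48565, loci of no assigned type, rose from 1.21 ± 0.412 to 70.6 ± 21.7 (adjusted p = 0.00446) and from 0.694 ± 0.491 to 30.0 ± 11.4 (adjusted p = 0.0444). In the annotation used here Gm48565 lies next to Hspa8, downstream of it on the same strand, and Gm10616 next to Polg on the opposite strand. Whether transcription running on from Hspa8 gave the rise of Gm48565 was not tested. The remaining gene has no symbol and was listed at 0 in both 60 min libraries.

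The count was 48 without control s1 (9 higher, 39 lower) and 146 without control s2 (22 higher, 124 lower), with 4 and 7 of the 9 genes among them. It was 2 without either 15 min library, 0 without either 60 min library, and 28 (23 higher, 5 lower) with median-of-ratios scaling over all genes above 0.

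**Figure D2:**
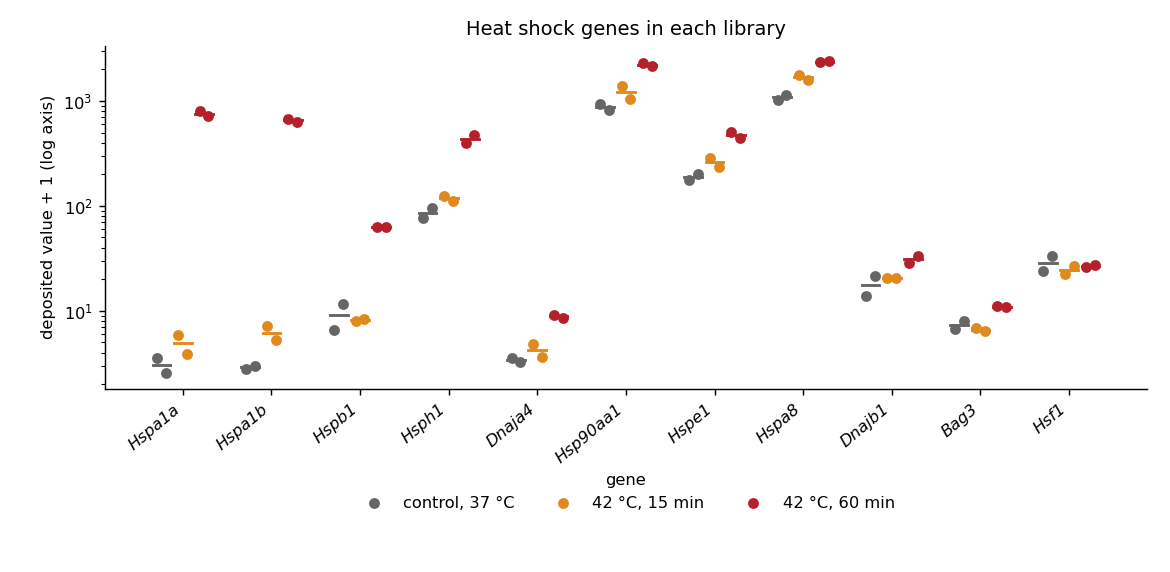
Deposited value plus 1 of 11 heat shock genes on a log axis, with 1 point per library and a bar at the mean of the 2 libraries of each group. Hspa1a lies at 713 and 794 before adding 1 in the 60 min libraries and at 4.92 or below in the other 4.

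Heat shock chaperones and co-chaperones were higher as a group at 60 min. Of 43 measured, 38 had higher values than in control, 3 rose over all genes tested, and 14 rose and 1 fell when adjusted over the list alone. The 14 included Hspb1, a small heat shock protein, at 8.11 ± 3.62 and 61.7 ± 0.435, Hsp90aa1, the inducible cytosolic Hsp90, at 876 ± 79.8 and 2215 ± 107, and Hspa8, the constitutive Hsp70, at 1089.8 ± 84.5 and 2359 ± 38.5. They also included Hspe1, the mitochondrial Hsp10, at 189 ± 17.5 and 476 ± 47.7, Dnajb1, an Hsp40 partner of Hsp70, at 16.8 ± 5.56 and 30.1 ± 3.31, and Dnaja4, another Hsp40, at 2.42 ± 0.219 and 7.89 ± 0.398. The member that fell was Ier5, an immediate early gene, from 47.4 ± 17.1 to 17.3 ± 1.85. Bag3, a co-chaperone, had 6.41 ± 0.955 and 9.92 ± 0.204, and Hsf1, the main heat shock transcription factor, 27.6 ± 6.73 and 25.7 ± 0.998, past neither threshold. The list's median log2 change was 0.55, with a camera adjusted p of 5.56e-23, and adjusted p = 0.564 with an estimated correlation. Random lists matched to it on mean expression had a median of 0.131 (5th to 95th percentile 0.0301 to 0.224). Without control s1, whose abundant genes were lower, the median was 0.51.

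The list of replication-dependent histones was lower. It also holds H1f0, a replacement linker histone whose message is polyadenylated. Of 19 measured, 18 had lower values than in control, 0 passed limma's test over all genes, and 15 fell when adjusted over the list alone. Among these, the linker histone Hist1h1c fell from 588 ± 144 to 136 ± 9.68, Hist1h1b from 809 ± 173 to 250.1 ± 41.9, Hist1h2bc from 46.9 ± 9.34 to 15.0 ± 1.53 and Hist1h2ac from 48.1 ± 8.31 to 12.8 ± 3.25. The median log2 change was −1.09, with a camera adjusted p of 1.28e-15, and adjusted p = 0.564 with an estimated correlation. The list summed to 7421 and 9051 in the controls and to 5116 and 3447 at 60 min.

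Most neural progenitor and radial glia genes were lower as well, while the list's summed signal was 3177 and 3583 in the controls and 3688 and 3132 at 60 min. Of 19 measured, 15 were lower, Btg2 fell over all genes tested, and 5 fell when adjusted over the list alone. Besides Btg2 these were Gas1, a modulator of hedgehog signalling, from 114 ± 5.61 to 30.9 ± 6.90, the proneural factor Neurog2, from 213 ± 74.5 to 72.0 ± 0.234, Eomes, a marker of intermediate progenitors, from 95.9 ± 8.39 to 43.2 ± 3.64, and Sox2, from 135 ± 9.79 to 70.2 ± 10.5. Fabp7, an abundant member that encodes a fatty acid binding protein of radial glia, had 319 ± 8.66 and 420.2 ± 61.0, past neither threshold. Neurog1, a related proneural factor outside the list, had 21.98 ± 6.09 and 2.56 ± 0.385 (adjusted p = 0.0791). The list's median was −0.34, with a camera adjusted p of 0.000352, and adjusted p = 0.571 with an estimated correlation. Without control s2, in which mitochondrial ribosomal RNA was highest, camera's adjusted p was 0.15, and with median-of-ratios scaling over all genes above 0 the median of neural progenitor and radial glia markers was −0.15. Without control s1 it was −0.73.

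Targets of p53 and genes of the NF-kB and cytokine response were also lower. Of 22 p53 targets 18 were lower, and Btg2, Bbc3, which encodes the pro-apoptotic protein PUMA (22.3 ± 2.63 to 7.20 ± 1.62), and Sesn1, a sestrin (31.9 ± 3.06 to 17.6 ± 0.494), fell when adjusted over the list alone, Btg2 also over all genes. All 15 NF-kB and cytokine genes measured were lower, and Nfkbiz (8.81 ± 1.19 to 3.13 ± 0.300) and Socs3, an inhibitor of cytokine signalling (9.40 ± 0.872 to 4.24 ± 1.05), fell when adjusted over the list alone. The medians were −0.29 and −0.33, with camera adjusted p of 0.00283 and 0.00464, and adjusted p = 0.564 with an estimated correlation for both. Without control s2 camera's adjusted p was 0.664 and 0.107, and with median-of-ratios scaling over all genes above 0 the medians were −0.12 and −0.17. Oligodendrocyte lineage genes, also at low values, were lower in 10 of 10 (median −0.43, camera adjusted p = 0.0533). Without control s1, which had the most genes at 1 or above, the median was −0.45 for p53 targets, −0.31 for NF-kB and cytokine response (adjusted p = 0.0177) and −0.0099 for oligodendrocyte lineage markers (adjusted p = 0.401).

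Genes of the integrated stress response (ATF4 and CHOP targets) differed in direction. Of 34 measured, 11 were higher and 23 lower, and 0 passed limma's test over all genes. Adjusted over the list alone, Cebpg, a transcription factor of the C/EBP family, rose from 129 ± 7.43 to 228 ± 2.71 and Trib3, a pseudokinase induced by ATF4 and CHOP, fell from 33.5 ± 19.4 to 7.05 ± 0.896. Atf4 itself had 410.2 ± 157 and 365 ± 7.02, Ddit3, which encodes CHOP, 112 ± 18.8 and 67.7 ± 5.08, and Ppp1r15a, which encodes the eIF2α phosphatase subunit GADD34, 25.6 ± 9.41 and 13.1 ± 1.74, past neither threshold. The median was −0.16, with a camera adjusted p of 0.379. The list passed without control s1 (median −0.40, adjusted p = 0.00514) and without 60 min s1 (median −0.43, adjusted p = 0.0481).

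Of 27 genes of ER chaperones and unfolded protein response, 15 were higher and 12 lower (median 0.054, camera adjusted p = 0.379), and Hspa5, the ER chaperone BiP, had 199 ± 70.8 and 134 ± 16.7. Without control s2 this list passed, with a median of 0.25 and adjusted p = 0.00129. Of 45 neuronal activity immediate early genes 29 were lower (median −0.28, camera adjusted p = 0.708). Btg2 fell over all genes, and adjusted over the list alone Rgs2, a regulator of G-protein signalling, rose from 17.2 ± 2.75 to 44.2 ± 5.90, and Jun rose from 93.3 ± 34.3 to 217 ± 14.1. Fos had 39.7 ± 23.0 and 47.6 ± 13.8, Egr1 47.4 ± 18.03 and 52.1 ± 2.77, Atf3 33.4 ± 19.7 and 37.3 ± 1.32, and Npas4, an activity-dependent transcription factor, 2.99 ± 1.05 and 9.15 ± 3.97, past neither threshold. Without control s1 the list's median was −0.60 (adjusted p = 0.000842) and without control s2 0.047 (adjusted p = 0.0129).

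**Figure D3:**
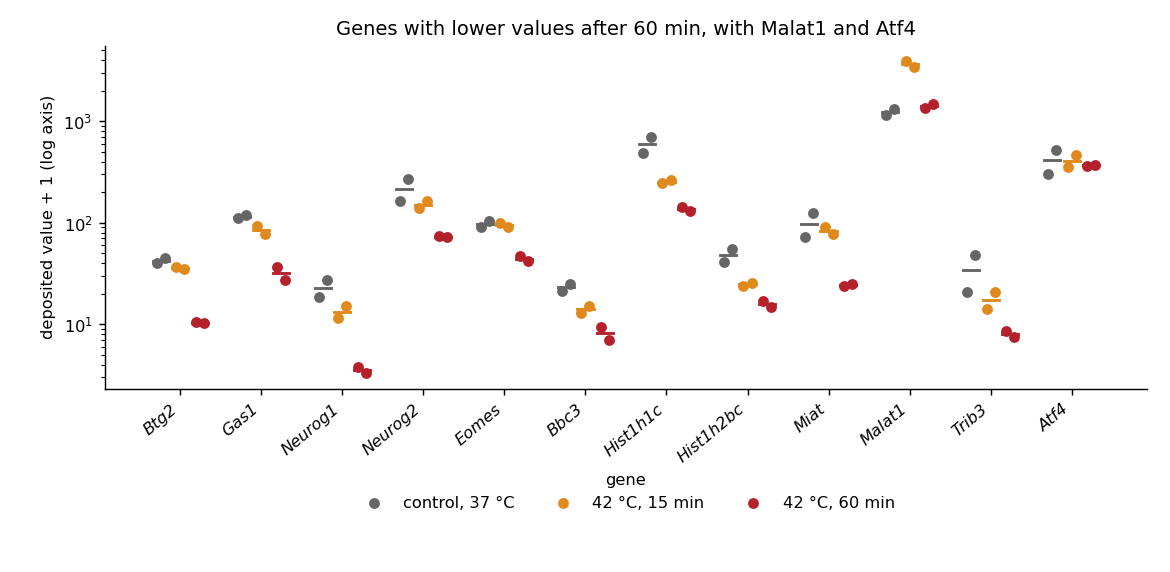
Deposited value plus 1 of 12 genes on a log axis, with 1 point per library and a bar at the mean of the 2 libraries of each group. Before adding 1, Btg2 lies at 9.21 and 9.59 after 60 min and at 34.0 or above in the other 4 libraries, and Malat1 has means of 1233, 3622 and 1416 in control, 15 min and 60 min.

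Ribosomal proteins, initiation factors and aminoacyl-tRNA synthetases were slightly higher at 60 min. Of 79 cytosolic ribosomal proteins 74 were higher (median 0.40), as were 35 of 38 initiation factors (median 0.26) and 20 of 22 aminoacyl-tRNA synthetases (median 0.24). Oxidative phosphorylation subunits (47 of 54, median 0.26), proteasome subunits (29 of 31, 0.26), splicing factors (27 of 36, 0.23) and pan-neuronal genes (17 of 24, 0.12) passed camera too. In these 7 lists 0 members passed limma's test over all genes or adjusted over the list alone. The ribosomal, initiation, synthetase, oxidative phosphorylation and proteasome lists hold 224 genes. Random lists matched to these genes on mean expression were higher as well, with a median of 0.217 (5th to 95th percentile 0.183 to 0.254). None of the 7 lists was matched singly. Rpl38 had 779 ± 6.29 and 1257 ± 27.8, Rps19 1812 ± 32.9 and 2891 ± 372, and Clk4, a kinase of splicing factors, 68.5 ± 3.05 and 144 ± 37.9. Camera's adjusted p ran from 9.13e-19 for ribosomal proteins to 0.041 for pan-neuronal genes. With an estimated correlation, adjusted p = 0.564 for the first 5 lists, 0.696 for splicing factors and 0.85 for pan-neuronal genes. Without control s1, whose abundant genes were lower, ribosomal proteins passed (median 0.23, adjusted p = 0.035) and the other 6 did not: adjusted p = 0.0968 for translation initiation factors, 0.0639 for cytosolic aminoacyl-tRNA synthetases, 0.158 for nuclear oxidative phosphorylation subunits, 0.17 for proteasome subunits, 0.0968 for splicing factors of the SR and hnRNP families and 0.263 for pan-neuronal and axonal markers. The median of the last turned to −0.062 without control s1, so its direction rests on that library, and it did not pass without 60 min s2 either (adjusted p = 0.539). With median-of-ratios scaling over all genes above 0, which moved the median of all genes by 0.16, the 7 medians ran from 0.32 for pan-neuronal and axonal markers to 0.60 for cytosolic ribosomal proteins. Mitochondrially encoded genes, among the most abundant, did not pass: 11 of 13 were lower (median −0.19, camera adjusted p = 0.458), and the median of mitochondrially encoded genes was 0.12 without control s1 and 0.0065 with this scaling.

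The series concerns elongation, and the list that holds its factors did not pass. Besides elongation and termination factors, that list names regulators such as Eef2k and eIF2α kinases such as Eif2ak4. Of 29 translation elongation and termination factors 17 were higher (median 0.12, camera adjusted p = 0.113). Eef1a1, which delivers aminoacyl-tRNA to the ribosome, had 4031 ± 345 and 6389 ± 932, Eef2, the translocation factor, 1139 ± 269 and 1510.1 ± 3.67, and Eef2k, the kinase that inhibits Eef2, 29.0 ± 5.43 and 34.1 ± 0.361. Eif2ak4, the eIF2α kinase GCN2, had 18.2 ± 0.3205 and 13.7 ± 0.00485, Gtpbp2, linked to stalled ribosomes, 65.8 ± 0.797 and 38.0 ± 2.95, and Actb 4819 ± 479 and 6066 ± 676. Without control s2 the list passed, with a median of 0.16 and adjusted p = 0.00663, and so it did with no filter on low values (adjusted p = 0.0477). In all, 12 of 32 lists passed camera at 60 min, 8 higher and 4 lower, and 0 with an estimated correlation or with fry.

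After 15 min at 42 °C the values farthest from control by p belonged to Malat1, small RNAs, pseudogenes and a locus of no assigned type, and none passed over all genes. Malat1, an abundant nuclear long non-coding RNA, had 1233 ± 118 in control and 3622 ± 355 at 15 min (SD, n = 2 each). The pseudogene Gm12941 had 7.51 ± 0.873 and 34.2 ± 0.0641, and the locus Gm10616 had 1.21 ± 0.412 and 8.98 ± 0.437. Adjusted over the list alone of 21 nuclear non-coding RNAs, Malat1 rose. The sum of Hspa1a and Hspa1b was 3.97 ± 0.616 in control and 9.10 ± 2.81 at 15 min.

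By limma 0 of 21954 genes passed, with a smallest adjusted p of 0.471, and 868 had an unadjusted p under 0.05, against 1097.7 by chance. With a replicate block by suffix 0 passed as well, and 1878 had an unadjusted p under 0.05. The log2 fold change was 1.55 ± 0.22 (SE) for Malat1 (adjusted p = 0.623), 2.05 ± 0.21 for Gm12941 (adjusted p = 0.471), 2.19 ± 0.28 for Gm10616 (adjusted p = 0.558) and −1.92 ± 0.22 for the pseudogene Gm48175 (adjusted p = 0.471). The other 6 of the 10 genes with the smallest p were small RNAs. Gm22704, Gm23345, Gm22177 and Gm23897 were listed at 0 outside the 15 min libraries, and Snora31 and Gm23322 were listed at 0 outside the controls. The count of genes was 41 without control s1 (2 higher, 39 lower) and 216 without control s2 (17 higher, 199 lower), and 7 (5 higher, 2 lower) with median-of-ratios scaling over all genes above 0.

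Heat shock chaperones were higher as a group at 15 min, and histones lower. Of 43 chaperone genes 35 were higher, with 0 past limma's test over all genes or adjusted over the list alone. Hspa1b had 1.91 ± 0.127 and 5.21 ± 1.37, Hspa8 1089.8 ± 84.5 and 1677 ± 144, and Cacybp, a co-chaperone, 104 ± 11.8 and 159.5 ± 7.42. The other 8 were lower, among them Hspb1 at 8.11 ± 3.62 and 7.19 ± 0.302 and Bag3 at 6.41 ± 0.955 and 5.61 ± 0.293. Of 19 histones 17 were lower and 9 fell when adjusted over the list alone, Hist1h1c from 588 ± 144 to 253 ± 8.59 and Hist1h2bc from 46.9 ± 9.34 to 23.7 ± 1.13 among them. The medians were 0.30 and −0.62, with camera adjusted p of 1.63e-10 and 3.48e-09, and adjusted p = 0.519 with an estimated correlation for both. Random lists matched to the chaperones on mean expression were higher as well, with a median of 0.193 (5th to 95th percentile 0.105 to 0.288), and the chaperone median lay at their 96.8 percentile. Their genes were drawn independently, which makes this range too narrow for genes that vary together. Those matched to the histones had a median of 0.260. The medians of heat shock chaperones and co-chaperones and of replication-dependent histones were 0.28 and −0.82 without control s1, whose abundant genes were lower, and 0.64 and −0.27 with median-of-ratios scaling over all genes above 0, which moved the median of all genes by 0.27.

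Camera called 16 of 32 lists at 15 min, 13 higher and 3 lower, and 0 with an estimated correlation or with fry. The higher lists included ribosomal proteins (71 of 79 genes, median 0.34), oxidative phosphorylation subunits (52 of 54, 0.34), splicing factors (34 of 36, 0.31), pan-neuronal genes (21 of 24, 0.27), proteasome subunits (30 of 31, 0.25), initiation factors (36 of 38, 0.25) and synthetases (22 of 22, 0.21). Tubulin and actin genes (median 0.22), cholesterol biosynthesis (0.19), cell cycle genes (0.15), NRF2 targets (0.13) and elongation factors (0.13) were the other higher ones. The ribosomal, oxidative phosphorylation, proteasome, initiation and synthetase lists hold 224 genes. Random lists matched to these genes on mean expression had a median of 0.264 (5th to 95th percentile 0.227 to 0.298). Camera compares a list with all other genes tested, not with genes of like expression. No list of this paragraph was matched singly. The median of cholesterol biosynthesis turned to −0.052 without control s1, and that of cell cycle and mitosis to −0.12 without 15 min s1 and −0.031 without control s2, so the direction of both rests on single libraries. Erythroid genes (9 of 9 lower, median −0.65) and NF-kB and cytokine genes (13 of 15 lower, −0.43) were lower, the median of NF-kB and cytokine response being −0.19 without control s1. With an estimated correlation the smallest adjusted p was 0.519, and the largest among these lists 0.837, for cell cycle genes. Without control s1, whose abundant genes were lower, 5 lists did not pass: translation elongation and termination factors (adjusted p = 0.183), oxidative stress response (NRF2 targets) (adjusted p = 0.609), cholesterol biosynthesis (adjusted p = 0.969), pan-neuronal and axonal markers (adjusted p = 0.691) and tubulin, actin and microtubule genes (adjusted p = 0.632). Without control s2, NF-kB and cytokine response (adjusted p = 0.284), cell cycle and mitosis (adjusted p = 0.284) and erythroid markers (adjusted p = 0.268) did not. Without 15 min s1 the first 2 of these had adjusted p = 0.177 and 0.138. With median-of-ratios scaling over all genes above 0 the higher lists of this paragraph had medians of 0.46 to 0.69, the last for cytosolic ribosomal proteins, and the lower ones −0.35 and −0.16. Oligodendrocyte lineage genes (9 of 10 lower, −0.43) and mitochondrially encoded genes (12 of 13 lower, −0.15) did not pass (camera adjusted p = 0.0754 and 0.528). The median of oligodendrocyte lineage markers was −0.052 without control s1, and that of mitochondrially encoded genes was 0.21 without control s1, 0.032 without 15 min s2 and 0.19 with this scaling.

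At 15 min the list of the integrated stress response (ATF4 and CHOP targets) depended on the control library. Its median was −0.076, with 15 of 34 genes higher and a camera adjusted p of 0.812. Without control s1 the median was −0.33 (adjusted p = 0.0213), and it was 0.19 without control s2 (adjusted p = 0.0193) and 0.089 without 15 min s1 (adjusted p = 0.0381). With median-of-ratios scaling over all genes above 0 it was 0.26 (adjusted p = 0.383). Atf4 had 406 ± 73.3 at 15 min, Ddit3 94.9 ± 19.3 and Trib3 16.3 ± 4.68, past neither threshold. Of 45 neuronal activity immediate early genes 36 were lower (median −0.17, camera adjusted p = 0.216), with a median of −0.51 without control s1 (adjusted p = 3.44e-07) and 0.13 without control s2 (adjusted p = 0.0186). The list passed without 15 min s2 too (median −0.36, adjusted p = 0.00335), and had a median of 0.02 without 15 min s1 and 0.13 with median-of-ratios scaling over all genes above 0, past the threshold in neither. Its member with the smallest p was Egr3, an early growth response factor, at 7.57 ± 0.842 and 4.05 ± 1.64, and, of the genes always named, Fos had 34.4 ± 15.9 at 15 min, Egr1 34.9 ± 9.71, Atf3 24.2 ± 7.70 and Npas4 2.62 ± 0.881.

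Of 27 genes of ER chaperones and unfolded protein response 14 were higher at 15 min (median 0.0056, camera adjusted p = 0.0754). The list passed without control s2 (median 0.26, adjusted p = 0.000382) and with median-of-ratios scaling over all genes above 0 (median 0.33, adjusted p = 0.0498) or no filter on low values (adjusted p = 0.00175). Edem1 and Syvn1, which serve ER-associated degradation, had 23.2 ± 4.22 and 16.5 ± 3.46 in control and 32.6 ± 2.93 and 11.3 ± 1.14 at 15 min, and Hspa5 had 180.1 ± 8.01. Among chaperones Hsp90aa1 had 1219 ± 233 at 15 min, Hsph1 117 ± 9.598, Hspb1 7.19 ± 0.302, Dnajb1 19.6 ± 0.0477 and Bag3 5.61 ± 0.293, and Hsf1 had 23.6 ± 2.93. Ppp1r15a had 23.6 ± 3.53, Eef1a1 5855 ± 802, Eef2 1362 ± 26.2, Eef2k 43.7 ± 11.2, Eif2ak4 13.7 ± 0.242 and Actb 6551 ± 459, and none of these genes passed over all genes or adjusted over the list alone.

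Between 15 and 60 min at 42 °C the inducible Hsp70 genes rose. Hspa1a went from 3.89 ± 1.45 to 753 ± 57.6 and Hspa1b from 5.21 ± 1.37 to 653 ± 30.0 (SD, n = 2 each), with a sum of 9.10 ± 2.81 and 1407 ± 87.5. Rnu3a was listed at 0 at 15 min. Of genes that did not pass over all genes, Hspb1 had 7.19 ± 0.302 and 61.7 ± 0.435, Hsph1 117 ± 9.598 and 433 ± 52.2, Btg2 34.6 ± 0.837 and 9.40 ± 0.263, and Malat1 3622 ± 355 and 1416 ± 97.3.

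By limma 4 genes passed, 3 higher and 1 lower. An unadjusted p under 0.05 was found for 1360 genes, 464 higher and 896 lower, against 1097.7 by chance. With median-of-ratios scaling over all genes above 0 it was found for 1047, and with a replicate block by suffix for 1972. The 4 genes were Hspa1b (log2 fold change 6.74 ± 0.22 SE, adjusted p = 0.000703), Hspa1a (7.30 ± 0.28, adjusted p = 0.00115), Rnu3a (adjusted p = 0.00379) and the gene without a symbol. Next by p were Gm48565 (adjusted p = 0.0854), then Hspb1, Btg2, Gm10616 and Gm14190, the last listed at 0 before 60 min (adjusted p = 0.0999 each), and Hsph1 and the pseudogene Gm19178 (adjusted p = 0.11 each). The count was 2 and 1 without 15 min s1 and s2, 0 without any 1 of the other 4 libraries, and 34 with median-of-ratios scaling over all genes above 0.

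Camera called 5 of 32 lists between the heated groups, and 0 with an estimated correlation or with fry. Heat shock chaperones were higher in 34 of 43 genes (median 0.17, adjusted p = 8.15e-07), with Hspa1a and Hspa1b past the test over all genes and 7 that rose and 1, Ier5, that fell when adjusted over the list alone. Progenitor genes were lower in 17 of 19 (median −0.43, adjusted p = 6.22e-06), and Btg2, Gas1, Eomes and Neurog2 fell when adjusted over the list alone, Gas1 from 83.6 ± 10.4 to 30.9 ± 6.90 and Eomes from 94.5 ± 5.78 to 43.2 ± 3.64. Of p53 targets 19 of 22 were lower (median −0.32, adjusted p = 2.14e-05), and Btg2 and Sesn1 fell when adjusted over the list alone, Sesn1 from 35.3 ± 0.774 to 17.6 ± 0.494. Histones were lower in 17 of 19 (median −0.32, adjusted p = 1.74e-05), and 5 fell when adjusted over the list alone, the one with the smallest p being H1f0, the replacement linker histone, from 322 ± 42.5 to 144 ± 48.7, followed by Hist1h1c, from 253 ± 8.59 to 136 ± 9.68. Genes of cholesterol biosynthesis were lower in 19 of 23 (median −0.21, adjusted p = 0.0254), and 0 passed limma's test over all genes or adjusted over the list alone. With an estimated correlation adjusted p = 0.984 for each of the 5. With median-of-ratios scaling over all genes above 0, which moved the median of all genes by −0.12, the median of heat shock chaperones and co-chaperones was 0.03 (adjusted p = 0.00161), and that of cholesterol biosynthesis −0.35 (adjusted p = 0.0985). The histone list did not pass without 60 min s2 (adjusted p = 0.0762), nor the cholesterol list without 60 min s1 (adjusted p = 0.232) or 15 min s2 (adjusted p = 0.0897). The integrated stress response (ATF4 and CHOP targets), with a median of −0.074 (camera adjusted p = 0.217), passed without 15 min s1 (adjusted p = 0.00136) and without 60 min s1 (adjusted p = 0.0333).

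Neuronal activity, unfolded protein and elongation genes did not pass as lists between 15 and 60 min. Of 45 neuronal activity immediate early genes 22 were higher (median −0.034, camera adjusted p = 0.795), and adjusted over the list alone Rgs2 rose from 18.9 ± 0.188 to 44.2 ± 5.90, Jun rose from 80.9 ± 6.72 to 217 ± 14.1 and Btg2 fell. Of 27 genes of ER chaperones and unfolded protein response 14 were lower (median −0.029, camera adjusted p = 0.712), with Dnajb9, an ER co-chaperone, at 13.3 ± 1.26 and 8.53 ± 0.792. Of 29 translation elongation and termination factors 17 were lower (median −0.08, camera adjusted p = 0.217), with Gtpbp2 at 72.0 ± 5.02 and 38.0 ± 2.95. With no filter on low values this last list passed (adjusted p = 0.0156), as did the integrated stress response (ATF4 and CHOP targets) (adjusted p = 0.0114). Over all genes Hsp90aa1, Hspa8, Dnajb1, Bag3, Hsf1, Fos, Egr1, Npas4, Atf3, Atf4, Ddit3, Ppp1r15a, Hspa5, Eef1a1, Eef2, Eef2k, Eif2ak4 and Actb did not pass between the heated groups.

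The changes at 15 and 60 min were compared across genes, which are not independent replicates. By limma 0 genes passed at both times, since 0 passed at 15 min, where 868 had an unadjusted p under 0.05, and 0 would be shared by independent lists. The correlation of the log2 changes was 0.547, and unchanged groups simulated against shared controls gave 0.501 on average and 0.526 at most in 100 draws. The covariance was 0.146, and 0.0844 in the simulation, a difference of 0.0617. The simulation gave all groups the same spread. The SD of the difference between the libraries of a group was 0.867 in control, 0.525 at 15 min and 0.607 at 60 min. Noisier shared controls raise both values by themselves, so the simulation cannot show an excess over sharing them. The controls were too few to split into groups of 2. With a different single control for each time the correlation was −0.177 or 0.0060. Without control s1 or control s2, both times share a single control library: the correlation was then 0.635 and 0.794, and 38 and 122 genes passed at both times. The number that unchanged groups would share in that case was not computed, so these counts say nothing of a shared effect.

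**Figure D4:**
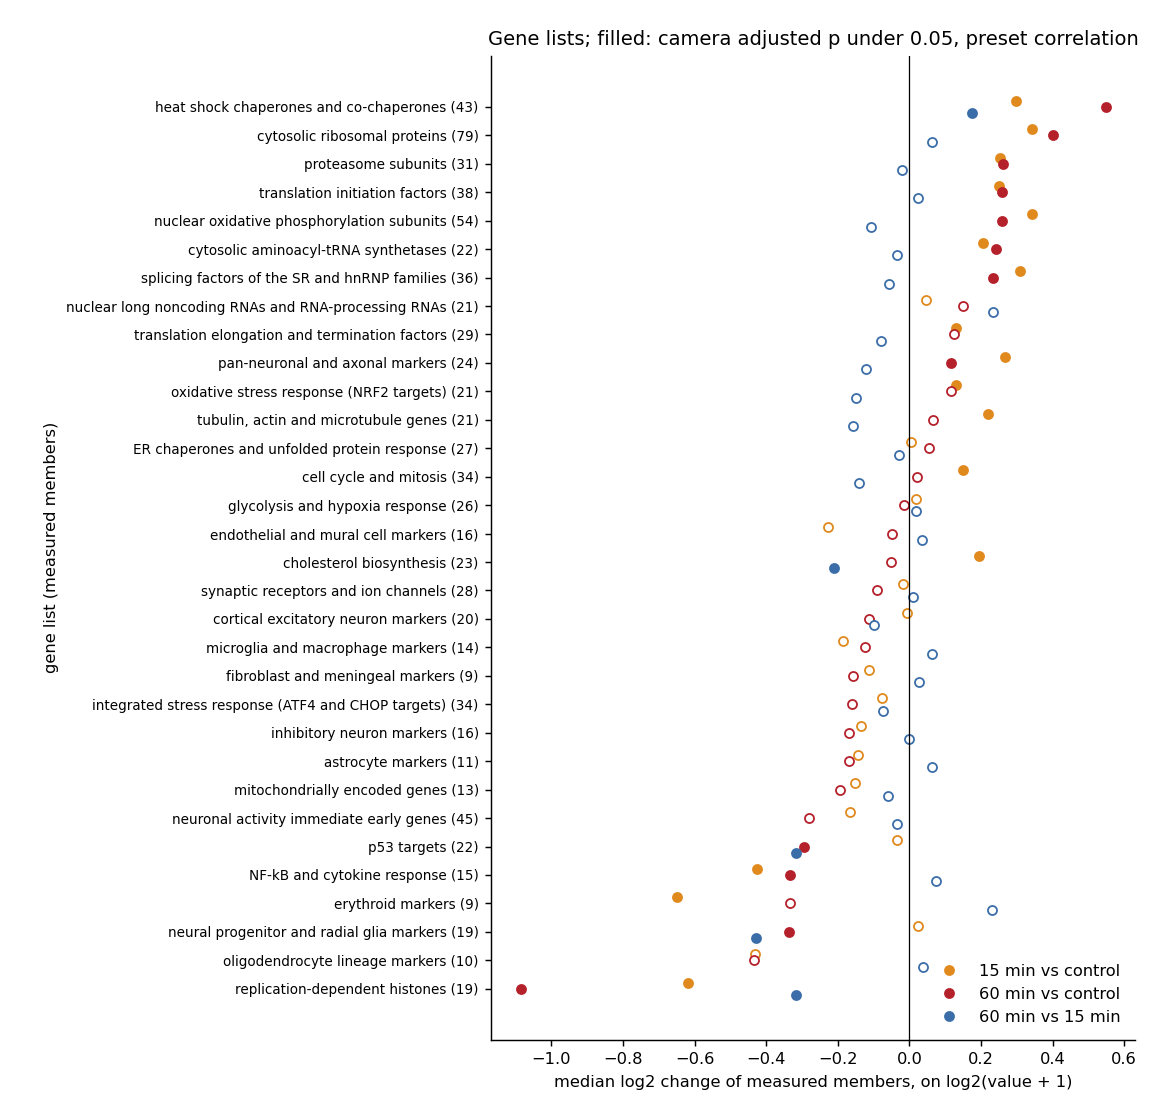
Median log2 change of the measured members of each of the 32 gene lists, on log2(value + 1), for the 3 comparisons; filled points passed camera at an adjusted p of 0.05 with the preset correlation. Heat shock chaperones have a median of 0.55 and replication-dependent histones of −1.09 at 60 min against control.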

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

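The number of genes listed at 0 in control s1 and the comparisons of non-coding genes on the opposite strand and without an expressed neighbour were chosen as tests only after the result was seen.

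The 2 heated groups differed in a direct test of 60 against 15 min, which drew attention to 4 genes and 5 lists. No control of 15 min is described, so these differences may include time in culture and are not attributed to heat alone. The log2 difference was 6.74 for Hspa1b, 7.30 for Hspa1a, 5.66 for Rnu3a, listed at 0 at 15 min, and −5.79 for a gene without a symbol, listed at 0 at 60 min. The list medians differed by 0.17 for heat shock chaperones, −0.32 for p53 targets, −0.21 for cholesterol biosynthesis, −0.32 for histones and −0.43 for progenitor genes. None of the 5 lists passed with an estimated correlation.

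Control s1 had 29309 genes at 1 or above, against 19035 to 21796 in the other libraries. Shallower sequencing, which would leave more genes at 0, cannot be told apart from other causes: 12298 genes were listed at 0 in control s1, within the range of 9778 to 13460 in the other libraries. A uniform low background such as genomic DNA may be present: olfactory receptor genes, which serve smell in the nose, had a median 2.24 times that of the highest other library. Whether such background came from DNA or from unspliced RNA was not tested, and no biological explanation was tested, since both controls have the same treatment.

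At 60 min both libraries had more long non-coding RNA genes at 1 or above (3319 and 3410) than at 15 min (2625 and 2839), and more pseudogenes (2082 and 2072, against 1467 and 1629). The tests took non-coding genes and pseudogenes that overlap no protein-coding gene and have a mean of at least 1 over the 6 libraries. An expressed gene was a protein-coding one with a mean of at least 5 in the heated libraries. The 2505 non-coding genes with no expressed gene within 10 kb had a median log2 change of 0.275. For the genes taken, transcription running up to 10 kb past the ends of expressed genes is therefore argued against as the whole cause. Those downstream of an expressed gene on either strand (258) differed from the 2505 by −0.071 (permutation p = 0.008, 95% interval −0.125 to −0.025), where 0.2 was needed. The 2 sets were not matched on expression, so this difference does not show that such transcription is absent downstream. On the same strand, genes downstream (149) differed from those upstream (103) by 0.048 (permutation p = 0.335, 95% interval −0.082 to 0.135), which argues against a shift of 0.2 there. On the opposite strand genes downstream (109) were higher than those upstream (283) by 0.139 (permutation p = 0.0061, 95% interval 0.033 to 0.248), short of 0.2. For those 109, transcription past gene ends cannot be told apart from other causes. Both downstream medians (0.202 and 0.215) were above both upstream medians (0.154 and 0.0756), and the strands were not pooled for a test of downstream against upstream. A uniform background cannot be told apart from other causes, because the olfactory receptor median was 1.22 times higher, between the bounds of 1.2 and 1.5 set for the test. Transcription running on for more than 10 kb and an effect of heat on these transcripts stay open and were not tested.

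Ribosomal proteins, initiation factors, synthetases, oxidative phosphorylation and proteasome subunits, 224 genes in all, were higher in both heated groups than in control. Their median lay at the 97.3 percentile of random lists matched on mean expression at 15 min and the 99.99 percentile at 60 min, outside the range set for the test. The matched lists were themselves higher, by 0.264 and 0.217 against 0.302 and 0.291. Whether a trend with expression level is the whole cause cannot be told from this, because these lists were taken up for being higher in these data. The random lists also drew genes independently, which makes their range too narrow for genes that vary together. Whether control s1 alone gave the difference cannot be told apart from an effect of heat: against control s2 alone the medians were 0.187 and 0.209, which keeps 62.0% and 71.6% and lies between the bounds set for the test. Only 1 control is then left.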

How the results depend on the processing

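Median-of-ratios scaling over the tested genes was chosen only after the data were seen. With so few libraries, single ones decide many calls, and depth is unknown; a lone library left in a group was assumed to vary like the other groups. Testing transcripts one by one was not run, because the table is per gene, and values as deposited became the main setting. Where no cause is given, the cause was not tested.

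Genes at 15 min against control (0) numbered 7 with median-of-ratios scaling over all genes above 0 and 0 to 216 when each library was left out. At 60 min against control (9) there were 5 with a pseudocount of 5, 5 without a filter, where more genes were tested, 28 with median-of-ratios scaling, 2 from the 4 libraries compared, where fewer samples set the spread, 17 at an adjusted p of 0.1, and 0 to 146 when each library was left out. Between 60 and 15 min (4) there were 34 with median-of-ratios scaling, 9 with quantile normalisation, 10 without the trend, 0 from 4 libraries, 9 at an adjusted p of 0.1, and 0 to 2 when each library was left out. Median-of-ratios scaling moved the median of all genes by 0.27, 0.16 and −0.12 in the 3 comparisons, quantile normalisation by 0.13, 0.12 and −0.0013, and rescaling without mitochondrial and small RNA genes by −0.11, −0.060 and 0.047. Genes called at both times (0) numbered 0 to 122 when each library was left out, where a single control library shared by both times gives shared calls by construction.

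Lists past camera (16, 12 and 5) numbered 0, 0 and 0 with an estimated correlation and 0, 0 and 0 with fry. Between 60 and 15 min there were 13 without a filter and 5 to 8 when each library was left out. The median turned from 0.19 to −0.052 for cholesterol biosynthesis at 15 min and from 0.12 to −0.062 for pan-neuronal genes at 60 min without control s1, and from 0.15 to −0.12 for cell cycle genes at 15 min without 15 min s1. The cell cycle median at 15 min turned negative without control s2 as well. When each library was left out the ranges were −0.052 to 0.39, −0.062 to 0.41 and −0.12 to 0.42. Median-of-ratios scaling over all genes above 0 turned no median of a list past camera, and ended the call for NF-kB and cytokine response at 15 min (adjusted p = 0.101), pan-neuronal and axonal markers at 60 min (adjusted p = 0.0752) and cholesterol biosynthesis between 60 and 15 min (adjusted p = 0.0985).

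With a replicate block by suffix the genes numbered 0, 8 and 4 and the lists 17, 12 and 5, where the list gained at 15 min was neuronal activity immediate early genes (adjusted p = 0.0246). Genes with an unadjusted p under 0.05 then numbered 1878, 2758 and 1972, against 868, 1830 and 1360 without the block. These counts therefore depend on how s1 and s2 are treated. Differences between s1 and s2 correlated across genes by 0.079, 0.10 and 0.22 between groups, which does not establish a pairing. Over all settings, single named genes lost a call in 83 cases and gained one in 32. They kept their side of the threshold in 5490 cases, most of them of genes not called in the main setting. Such genes had no call to lose, so the 5490 cases do not measure how stable the calls were. All 83 losses fell on the few named genes called in the main setting. Lists past camera kept their direction and call in 336 cases, lost the call in 90 and reversed direction in 3. The sign of a named gene changed in 62 of the cases of single genes, none of them a called value.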

Other observations

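The test on AU-rich elements was written before its result was seen; Miat, Polg, Rpph1, Rmrp and the genes without a symbol were singled out after their values were seen.

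Some transcripts outside the groups above had values that stood apart at 60 min. Miat, a nuclear long non-coding RNA, fell from 97.1 ± 36.4 in control to 23.5 ± 0.609 (SD, n = 2 each) and Snhg12, a host of small nucleolar RNAs, rose from 38.2 ± 4.37 to 78.7 ± 12.7, both adjusted over the list alone of 21 nuclear non-coding RNAs, which as a list did not pass (camera adjusted p = 0.0687). Fgfr3, a growth factor receptor of astrocytes and progenitors, fell from 223 ± 9.70 at 15 min to 109 ± 28.6 at 60 min adjusted over the list alone of 11 astrocyte genes. Polg, the mitochondrial DNA polymerase beside Gm10616, had 75.3 ± 1.32 in control, 58.3 ± 0.474 at 15 min and 43.6 ± 1.57 at 60 min. Summed signals were 22.6 to 44.3 for oligodendrocyte lineage genes, 93.6 to 140.3 for inhibitory neuron genes and 1326 to 1661 for excitatory neuron genes.

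A gene without a symbol (ENSMUSG00002076161) had 37749 in control s2 and 281 to 2224 in the other libraries. Another (ENSMUSG00000119584) had 6278 and 5049 in the s1 libraries at 15 and 60 min and 159 to 765 in the other 4. The small RNAs Rpph1 and Rmrp had 13651 and 9033 in control s2, against at most 7397 and 3034 elsewhere.

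The fall of short-lived messages such as Btg2 and Ier5 raised the hypothesis that transcripts with AU-rich elements decay while synthesis falls. Among 10037 coding genes, the 733 whose 3′ UTR held ATTTATTTA differed from length-matched genes without it by 0.019 in median log2 change from 15 to 60 min (permutation p = 0.125), and those with the shuffled motif TTAATATTT by 0.0076 (permutation p = 0.619). The difference was not negative, and it was 0.018 when matched on GC content, so the test argues against a fall of genes with this motif as a class. Whether the motif marks short-lived messages in these cells was not tested, so their decay stays open.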
